A study of Rattus norvegicus with 8 samples.

How the data were processed

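RNA from rat kidney was measured on 8 two-colour oligonucleotide arrays from Agilent. Per the labels, the Cy5 channel held the sample, the Cy3 channel held normal kidney RNA as a common reference, and RNA was amplified from a small input before labelling. The 4 E. coli arrays held kidney samples taken 1, 2, 4 or 6 weeks from the injection of bacteria, and the 3 saline arrays held samples of weeks 1, 2 and 4. A saline array of 6 weeks was not analysed here. On the remaining array, normal kidney RNA was in both channels.

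The deposited values were log10 ratios of Cy5 over Cy3, 1 per feature and array. The direction follows from the dyes in the labels. The base of 10 is not stated there and was taken from the software and from the lowest value, which was exactly -2 on all 8 arrays. Image quantification used Agilent Feature Extraction 7.1, per the labels. Its dye normalization, scale and centring are not given in the sources used here. The deposited medians lay between -0.00474 and 0. Signal levels were not used here, so signal over background is unknown, and the number of arrays limits the precision. All ratios were converted to log2 for this work.

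The table held 21575 rows. A symbol table of the array named 1 gene for 12750 rows, several for 5 and none for 8820, and 12720 rows had a gene of the RefSeq table of assembly GRCr8, which changed 0 symbols. Values of exactly 0 numbered 343 to 635 per array, against 96 to 129 other values within 0.001 of 0, so they were treated as having no usable ratio. This left 815 rows out of the comparison of E. coli with saline. Unnamed rows below -1 on the log10 scale on at least 6 arrays numbered 464 and were left out as resembling control spots. Probes of 1 symbol were averaged, which applied to 2266 genes, and rows without a single symbol were kept as unnamed probes. This gave 17260 features (9484 genes and 7776 unnamed probes) over the 7 treated arrays and 17233 over all 8.

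Tests used limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with Benjamini-Hochberg adjustment over all features, two-sided. A call was an adjusted p under 0.05. E. coli was compared with saline without a week term, with 5 residual degrees of freedom. Contrasts with normal used all 8 arrays and assumed that the single normal array varied like the others. Week trends had a slope per treatment and 3 residual degrees of freedom. The labels give 1 array per treatment and week and whether its RNA came from 1 kidney or a pool is not given in the sources used here. The weeks served as the samples of a treatment. The p-values of a difference between groups therefore set it against the spread within an arm, over samples and weeks together.

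The 29 gene lists, chosen for kidney infection, scarring, nephron segments and other cell types, were tested with camera at a preset correlation of 0.01 between genes, again with an estimated correlation, and with fry. At single weeks there was 1 array per arm and no test. List medians were set beside those of 10000 random lists of equal size, not matched on expression because no level was available.

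Named genes followed a rule set before the data were examined. It took the 15 largest called changes in each direction with the same sign at 1, 2 and 4 weeks. Where fewer than 5 passed, it took the 10 largest changes with an unadjusted p under 0.01, named as not passing. It also took up to 4 genes of lowest p per list, the 5 highest and 5 lowest differences at each week, and for other comparisons the 8 largest called changes each way or the 5 of lowest p. Other genes are said to have been chosen after their values were seen.

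The tests were tried on simulated data with the means and residual spread of the comparison of E. coli with saline, over 17260 features in 10 runs with 200 changed features each. They recovered 81.5% of 2-fold and 96.1% of 4-fold changes, and 5.13% of calls were false. These simulations had independent noise and no change over weeks, and the changed features were drawn at random, whatever their spread. In the data 19 of the 175 features at least 2-fold higher were called, so the recovered shares do not carry over to the data. A T cell list raised by 0.5 (log2) was called in 10 of 10 runs, and 1 list call was made over all runs without an effect. Of slopes of 0.5 per week, added to features drawn at random, 85.4% were recovered, with 96 false slope calls over the 10 runs. In the data, slopes near this size did not always pass. By limma, Jchain had a slope of 0.49 (adjusted p = 0.302) and Il1b of -0.46 (adjusted p = 0.098). This share therefore does not carry over to the data either.

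Alternatives were median centring, scaling to 1 spread, leaving out features over 1.5-fold off on the normal array, each probe on its own, robust variance moderation, other treatments of week, ratios against 0 in place of the normal array, and leaving out each array in turn. Keeping exact zeros, keeping the control-like rows and fitting a slope per treatment were added after the data were seen. All titles carry the same replicate number, so no pairing of samples was taken from it.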

Results

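The data were expression ratios from the kidneys of female Wistar rats in a model of pyelonephritis, a bacterial infection of the kidney that can leave scars. Live E. coli of 1 strain, or saline, was injected into the renal cortex, and a small piece around the injection site was taken weeks later. There were 4 E. coli arrays (1, 2, 4 and 6 weeks), 3 saline arrays (1, 2 and 4 weeks) and 1 array with normal kidney RNA in both dyes. Each treatment and week had 1 array, and whether it held 1 kidney or a pool is not given in the sources used here. The p-values of a difference between groups therefore set it against the spread over samples and weeks within an arm. They do not measure how steady the difference was from week to week, and values at a single week have no replicate. All values below are on the log2 scale, converted from deposited log ratios whose base of 10 was inferred. Across features, the normal array itself correlated with the 7 other arrays at r = 0.68 to 0.86. How far this shared part cancels in differences between arrays was not tested.

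The first comparison asked which genes differed between infected and saline-injected kidneys. Of the genes listed beforehand as T cell markers 8 of 25 passed as higher after E. coli, and of those of B and plasma cells 1 of 8. Cd3g, a chain of the T cell receptor complex, was higher by 2.34 ± 0.23 (SE; n = 4 and 3; adjusted p = 0.0235), or 5.05-fold. Cxcl13, which attracts B cells, was higher by 1.71 ± 0.08 (adjusted p = 0.0015) and had the lowest p of all features. Cd79b, part of the B cell receptor, was higher by 1.60 ± 0.15 (adjusted p = 0.0232).

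In all, 32 of 17260 features passed, 26 higher and 6 lower, and 21 of the higher and 2 of the lower had a gene name. The surface proteins Cd5, Cd3e, Cd2 and Cd4, listed beforehand as T cell markers, rose by 2.07, 1.23, 1.22 and 1.02. Whether T cells were their source was not tested. Lat, an adaptor in T cell receptor signalling, rose by 1.23. The lymphoid phosphatase Ptpn22 rose by 1.38 and Ptprcap by 1.24. Ltb, the lymphotoxin beta chain, rose by 1.60, and Spib, a transcription factor of B cells, rose by 1.68. Cd53, a tetraspanin of leukocytes, rose by 1.38. Clec9a, a lectin of dendritic cells, rose by 1.06, and the aspartic protease Ctse rose by 1.12. The 2 named genes that passed downwards were Star, which brings cholesterol into mitochondria for steroid synthesis, at -0.75 ± 0.07 (adjusted p = 0.0235), and Stxbp4 at -0.70 ± 0.08 (adjusted p = 0.0384). Of genes lower without passing, Slc25a44 had a difference of -1.03 (adjusted p = 0.181), Vom2r8 of -0.92 (adjusted p = 0.171), Kalrn of -0.83 (adjusted p = 0.208) and Art5 of -0.83 (adjusted p = 0.05003).

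**Figure D1:**
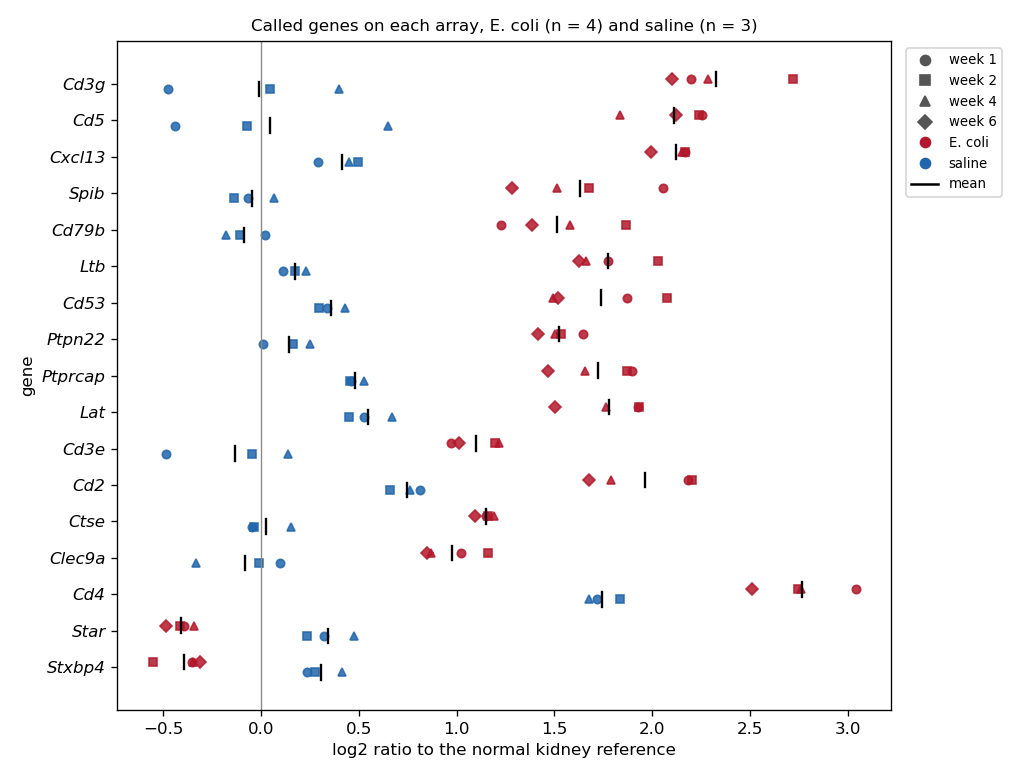
Log2 ratio to the normal kidney reference (horizontal axis) of the 17 called genes named by rule (vertical axis), 1 point per array, with marker shape for week, colour for treatment and a black bar for the mean of each treatment. All 4 E. coli points of Cxcl13 lie between 1.99 and 2.17, above its 3 saline points, and Star and Stxbp4 lie lower after E. coli. The ratios are not corrected for the normal array, where these genes read from -0.48 (Ctse) to 1.36 (Cd4).

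At an unadjusted p under 0.05 there were 2472 features. Of the other 34 splits of the 7 arrays into 4 and 3, 2 gave more (3029 and 2739), so that wider count was not beyond every regrouping. Both kept the E. coli arrays of 1, 2 and 4 weeks together, and so still hold part of the contrast with saline. They therefore cannot show whether a grouping unrelated to treatment reaches 2472. The count of 32 moved when single arrays were left out. It was 10, 5, 4 and 38 without the E. coli array of 1, 2, 4 and 6 weeks, and 5, 1 and 8 without the saline array of 1, 2 and 4 weeks. It was 0 with week as a block and 83 after scaling the arrays to 1 spread. All 32 kept their direction with week as a block, which follows from each having the same sign at 1, 2 and 4 weeks. With a slope per treatment, a fit added after the data were seen, the count was 784 (631 higher, 153 lower). That fit tests the difference at the mean of weeks 1, 2 and 4, not between the means of all arrays of each arm. Ptprc, C3, Mmp7 and Tgfb1, which did not pass without slopes, were higher by 1.72, 2.74, 4.39 and 0.93 at that time.

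The next comparison asked how whole gene groups differed between E. coli and saline. The T cell list was higher in 24 of 25 measured genes, with a median of 0.66 (camera adjusted p = 2.62e-19; adjusted p = 0.111 with an estimated correlation). Of its genes 8 passed over all features and 17 when adjusted over the list alone, among them Cd6 at 0.66 and Zap70 at 0.98. The list of B and plasma cell markers was higher in 7 of 8 genes, with a median of 0.69 (camera adjusted p = 5.24e-06; adjusted p = 0.316 with an estimated correlation). In it 1 gene passed over all features and 5 adjusted over the list alone. Jchain, which joins secreted antibodies, had the largest difference there at 5.12 ± 0.71, with an adjusted p of 0.0638. The macrophage and myeloid list was higher in 25 of 26 genes, with a median of 0.62 (camera adjusted p = 2.09e-13; adjusted p = 0.316 with an estimated correlation). None of its genes passed over all features and 17 did adjusted over the list alone, led by the leukocyte phosphatase Ptprc at 1.57 and Coro1a at 1.61.

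Complement genes were higher in 18 of 20 cases, with a median of 0.77 (camera adjusted p = 3.04e-08; adjusted p = 0.336 with an estimated correlation). Adjusted over the list alone 13 were higher and 1 lower, and over all features 0 passed. C3 had a difference of 2.39, C6 of 2.18, Cfd of 2.996 and C9 of -0.40. Chemokines had a median of 0.57 and were higher in 22 of 25 genes (camera adjusted p = 1.18e-08; adjusted p = 0.316 with an estimated correlation). Cxcl13 was the 1 chemokine that passed over all features, and 6 were higher and 1 lower adjusted over the list alone. Ccl19 and Ccl20 had differences of 2.11 and 2.07. Antigen presentation genes had a median of 0.48 and were higher in 17 of 19 genes (camera adjusted p = 1.52e-09; adjusted p = 0.316 with an estimated correlation), with 0 past the threshold over all features and 10 adjusted over the list alone. Cd80 had a difference of 1.76 and the immunoproteasome subunit Psmb8 of 1.16.

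Cytokines and innate sensing (median 0.48, 21 of 27 higher; camera adjusted p = 1.71e-06), acute phase and antimicrobial genes (0.48, 15 of 19; camera adjusted p = 0.000121) and interferon-stimulated genes (0.29, 20 of 21; camera adjusted p = 8.06e-07) were also higher. For each of these 3 lists the adjusted p = 0.336 with an estimated correlation. None of their genes passed over all features, and 6, 3 and 0 did adjusted over the list alone. Il1b had a difference of 2.21 and the antiprotease Slpi of 2.28.

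Lists of scarring genes were higher by camera at the preset correlation, while none of their members passed over all features. The extracellular matrix list had a median of 0.35 and was higher in 29 of 31 genes (camera adjusted p = 1.71e-06; adjusted p = 0.336 with an estimated correlation), with 1 gene past the threshold adjusted over the list alone. Sparcl1 had a difference of 0.60 and Loxl1, which crosslinks elastin, of 0.56. Tnc averaged 0.42, but its 4 probes differed in sign. Matrix turnover genes had a median of 0.19 (camera adjusted p = 0.0073; adjusted p = 0.341 with an estimated correlation), with 2 higher and 1 lower adjusted over the list alone. The protease Mmp7 had a difference of 4.01 ± 0.65 (adjusted p = 0.0867) and the inhibitor Timp3 of -0.33. The TGF-beta and growth factor list had a median of 0.17 (camera adjusted p = 0.0273; adjusted p = 0.427 with an estimated correlation), with Tgfb1 at 0.75. Its call was lost without the E. coli array of 1 or 4 weeks (adjusted p = 0.0812 and 0.05003) and without the saline array of 1 or 2 weeks (adjusted p = 0.117 and 0.105). Myofibroblast and smooth muscle genes had a median of 0.15 (camera adjusted p = 0.000901; adjusted p = 0.336 with an estimated correlation), with S100a4 at 1.24 and Des at 0.93. Tubular injury genes had a median of 0.47 and were higher in 19 of 25 genes (camera adjusted p = 4.98e-05; adjusted p = 0.467 with an estimated correlation), with Cd44 at 1.04 and Lcn2 at 1.2504. In these last 3 lists 0 genes passed adjusted over the list alone. At week 4 alone the medians were below those at week 1. They were 0.18 against 0.63 for extracellular matrix, 0.21 against 0.54 for matrix turnover and 0.05 against 0.37 for TGF-beta and growth factors. For myofibroblast and smooth muscle they were 0.11 against 0.41, and for tubular injury 0.09 against 0.86.

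Lists of tubule and metabolic genes were lower by camera on the 7 arrays together, though at week 4 alone 2 of these 4 lists had medians above 0. Proximal tubule markers were lower in 51 of 57 genes, with a median of -0.18 (camera adjusted p = 0.00154; adjusted p = 0.524 with an estimated correlation). Their call was lost without the saline array of 1 week (adjusted p = 0.117) and without features over 1.5-fold off on the normal array (adjusted p = 0.0552). Markers of the loop, distal tubule and collecting duct were lower in 27 of 31 genes, with a median of -0.23 (camera adjusted p = 0.000262; adjusted p = 0.336 with an estimated correlation). Fatty acid oxidation genes were lower in 27 of 29 cases, with a median of -0.15 (camera adjusted p = 6.01e-05; adjusted p = 0.421 with an estimated correlation). Mitochondrial genes were lower in 32 of 33 cases, with a median of -0.14 (camera adjusted p = 2.91e-06; adjusted p = 0.427 with an estimated correlation). At week 4 alone the proximal tubule median was 0.14 (40 of 57 higher), that of fatty acid oxidation 0.03 (17 of 29 higher), of mitochondrial genes -0.03 (15 of 33 higher) and of the distal segments -0.09 (11 of 31 higher). In each of these 4 lists 0 genes passed, over all features or adjusted over the list alone. Gatm, the first enzyme of creatine synthesis, had a difference of -0.78, Egf of -0.49 and Idh3a of -0.41. The leukocyte lists were higher on the same arrays, with medians of 0.62 for the macrophage and myeloid list and 0.66 for the T cell list.

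The other 11 lists were not called on all 7 arrays. Proliferation genes were called lower without the E. coli array of 1 week (adjusted p = 0.00231) and adrenal markers lower without the E. coli or the saline array of 4 weeks (adjusted p = 0.0378 and 0.0419). Neutrophil and mast cell markers were called higher without the saline array of 2 weeks (adjusted p = 0.0155) and adipose markers higher without that of 4 weeks (adjusted p = 0.0227). Their medians were -0.08 for the renin-angiotensin system, 0.16 for neutrophil and mast cells, -0.04 for podocyte and mesangial cells, 0.01 for endothelium, -0.04 for proliferation, -0.01 for oxidative stress and 0.00 for retinoid metabolism. Erythroid, adipose, skeletal muscle and adrenal markers had medians of -0.05, 0.04, -0.08 and -0.05. Skeletal muscle and oxidative stress genes had means above 0 (0.03 and 0.0027). With an estimated correlation 0 of 29 lists were called, the lowest adjusted p being 0.111, and fry called 4 (T cells, B and plasma cells, chemokines and antigen presentation). Of the 35 ways to split the 7 arrays into 4 and 3, 8 (the real one included) called at least 18 lists. This limits what the preset-correlation calls show. Most of the others among them kept 3 E. coli arrays together and so still hold part of the contrast, which is why the count cannot decide on chance.

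At single weeks, features at least 2-fold higher after E. coli than after saline numbered 750, 399 and 215 at 1, 2 and 4 weeks, and features at least 2-fold lower 103, 185 and 61. Mmp7 differed by 5.67, 4.07 and 3.56 at the 3 weeks and Cfd by 4.54, 3.22 and 2.62. Jchain differed by 3.02, 5.57 and 5.72. The lowest values were Smarca1 at week 1 (-2.73), Reg3b at week 2 (-3.88) and Ptprz1 at week 4 (-1.95), none of which had that sign at all 3 weeks. The T cell list had medians of 0.91, 0.69 and 0.56, complement of 1.29, 1.03 and 0.31, and the extracellular matrix of 0.63, 0.35 and 0.18. Each of these list medians lay at or above the 99.99th percentile of random lists. Relative to the normal array, complement stood at 1.36, 1.20 and 0.80 after E. coli and at 0.08, 0.28 and 0.40 after saline. The matrix list stood at 0.87, 0.49 and 0.36 after E. coli and at 0.03, 0.16 and 0.28 after saline. The T cell list stood at 0.89, 0.54 and 0.55 after E. coli and at -0.09, 0.07 and 0.03 after saline. Proximal tubule markers had medians of -0.36, -0.48 and 0.14. Relative to the normal array they stood at -0.12, -0.12 and -0.49 on the saline arrays and at -0.45, -0.55, -0.35 and -0.15 on the E. coli arrays.

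**Figure D2:**
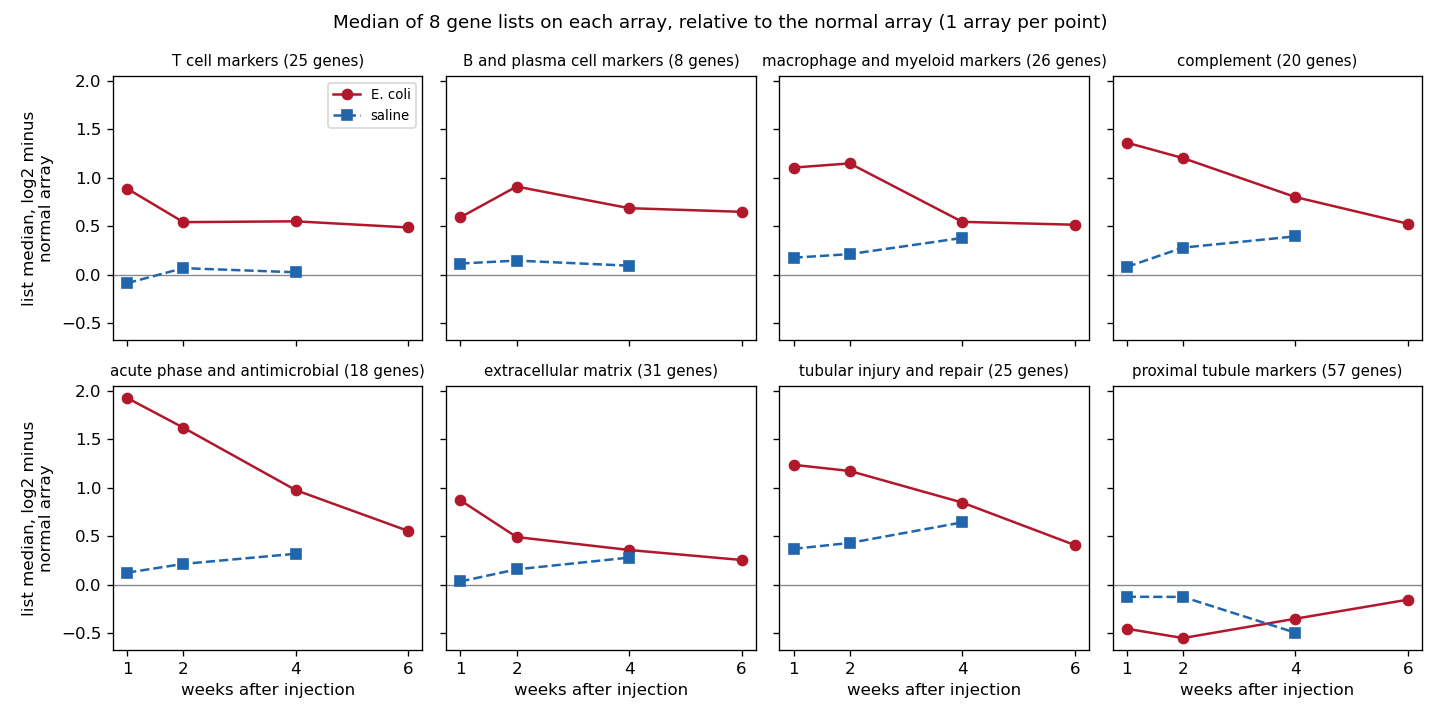
Median log2 ratio minus the normal array (vertical axis) of 8 gene lists against weeks after injection (horizontal axis), 1 array per point, for E. coli (circles, solid lines) and saline (squares, dashed lines). On the E. coli arrays acute phase genes go from 1.92 at week 1 to 0.55 at week 6, while T cell genes stand at 0.89 and 0.49.

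The comparison with normal kidney asked what differed from normal tissue. After E. coli, 10 of 17233 features were called, all higher. Cxcl13 rose by 1.93 ± 0.11 (adjusted p = 0.0029), Ltb by 1.87, Ptpn22 by 1.76, Ctse by 1.63, Sit1 by 0.97 and Cd6 by 0.96. For Cd6 most of this rests on the normal array, which read -0.73. The E. coli arrays, also ratios to normal RNA, read 0.14 to 0.29. After saline, 2 features were called, Slx9 at 3.11 ± 0.16 (adjusted p = 0.0018) and an unnamed probe. The same 2 were called after E. coli, with Slx9 at 3.29. On the normal array, where both dyes held the same RNA, Slx9 read -2.78 and the probe -2.57, while on the 7 other arrays, with the same reference in Cy3, they read 0.14 to 0.61 and 0.18 to 0.32. The other unnamed probes called after E. coli read -1.15 and -1.51 on the normal array. They read 0.05 to 0.12 and -0.11 to 0.08 on the E. coli arrays. On the saline arrays they read -0.26 to 0.09 and -0.28 to -0.01. Leaving out features over 1.5-fold off on the normal array removes Slx9, all these unnamed probes and Cd6.

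With that filter 4 features were called for E. coli and 0 for saline. The E. coli count was 49 (44 higher, 5 lower) after scaling, and it was 6, 5 and 24 without the E. coli array of 2, 4 and 6 weeks and 5 without the saline array of 2 weeks. The saline count was 4 without the saline array of 4 weeks. At an unadjusted p under 0.05 there were 2460 features for E. coli and 1066 for saline.

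The last comparison asked whether expression changed with time. By limma, 0 features passed for a slope over the E. coli weeks, with 2770 at an unadjusted p under 0.05, of which 1725 were falling and 1045 rising. The lowest p belonged to Cebpd, a transcription factor of the acute phase response, at -0.35 ± 0.02 per week (adjusted p = 0.0691). Fibronectin, Fn1, had a slope of -0.34 per week (adjusted p = 0.0729), and Wnt4, Fcgr2b and Cyp1b1 had slopes of -0.36, -0.33 and -0.43 (adjusted p = 0.0834). For the difference in slope between E. coli and saline 0 features passed, with 2881 at an unadjusted p under 0.05. Fn1 (-0.52 per week), Fcgr2b (-0.64), Cebpd (-0.44) and Nfkbie (-0.50) came first, each with an adjusted p of 0.159, followed by Klf5 at -0.59.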

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

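The tests of Slx9, of the proximal tubule markers and of the slopes of called genes were chosen after their results were seen, as were the counts of splits for the week trend, for unadjusted p and for the fit with a slope per treatment, a fit that was itself added after the data were seen. The counts of splits for called features and for gene lists were planned before theirs were seen.

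Of the 35 splits of the 7 arrays into 4 and 3, only the real one (1 split) called as many as 32 features between E. coli and saline, and the highest other split called 1. The real grouping thus stood apart from every other split, at the lowest share that 35 splits allow (0.0286). Chance is not excluded by this, because the splits take no account of the weeks that both arms share. With week as a block 0 features were called (limma, lowest adjusted p = 0.177). For the gene lists the real grouping did not stand apart: 8 splits, the real one included, called at least 18 lists. The highest other split called 21, and it set the E. coli arrays of 1, 2 and 4 weeks with the saline array of 2 weeks. Most of the others that reached 18 also kept 3 E. coli arrays together, so they still hold part of the contrast with saline. A split that mixed the arms (E. coli of 4 and 6 weeks with saline of 1 and 4 weeks) called 18 as well. The count therefore cannot decide on chance for the lists. For the difference in week trend the real split called 0, which all 35 splits reached, and the highest other split called 22.

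Slx9 and an unnamed probe were called higher than normal after both E. coli and saline. On the normal array Slx9 read -2.78 with the same RNA in both dyes, beyond the lowest 0.1% of that array, while 0 of the other 7 arrays put either feature outside their central 95%. The 7 arrays also carried normal kidney RNA in Cy3, and there the 2 features read at most 0.61, where a rise of 3.11 or 3.29 for Slx9 without dye bias would read about that much. This argues against such a rise. An odd value on the normal array, and a rise offset by a dye bias of about the same size at these probes, cannot be told apart, because no repeat of that array was analysed here.

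Proximal tubule markers were lower after E. coli at 2 weeks (-0.48) and higher at 4 weeks (0.14), a difference between weeks that was not tested. The 4-week saline array differed by -0.37 from the nearer of the other saline arrays, and the 4-week E. coli array (-0.35) lay between those of 2 and 6 weeks. The change of sign may therefore come from the 4-week saline sample. Whether that sample, its piece of tissue or a late effect of the injection set it apart cannot be decided from 1 array. With the normal array subtracted, the 4-week saline array correlated at r = 0.47 and 0.49 with the other saline arrays. With the E. coli arrays it correlated at r = 0.49 to 0.65. The saline arrays of 1 and 2 weeks correlated with each other at r = 0.45, so a low correlation within saline was not particular to week 4. Some other list medians against normal also set the 4-week saline array apart from those of 1 and 2 weeks. Fatty acid oxidation read -0.18 against 0.003 and -0.03, and interferon-stimulated genes 0.38 against 0.01 and 0.06. Other lists did not, such as T cell markers at 0.03 against -0.09 and 0.07.

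On the E. coli arrays the called genes changed little with week, with a median absolute slope of 0.055 per week in the 19 that were at least 2-fold higher. The slopes in this paragraph are those of the E. coli arrays alone. The difference from saline was not steady in all called genes. For Cd5 it was 2.69, 2.31 and 1.18 at 1, 2 and 4 weeks, and for Cxcl13 1.87, 1.67 and 1.70. A slope per treatment was then fitted, so that change over weeks no longer counted as noise. The 19 features at least 2-fold higher with the lowest p in that fit had a median absolute slope 3.32 times as large, and 6 were shared. Among the others were Fcgr2b, Cebpd, Ptprc and Gpnmb, the last chosen after its value was seen. The ratio decides nothing, because the test without week favours small slopes by construction and all 175 features at least 2-fold higher already had a median absolute slope of 0.166. With those slopes 784 features were called, against at most 356 in another split, and 1 of 35 splits (the real one) reached that count. The split that gave 356 set the E. coli array of 6 weeks with the saline arrays. Whether the called lymphocyte genes are steadier than other leukocyte genes is left open.

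A single E. coli array lay far from the others for 5 of 132 named genes and 4 of 29 lists, where chance gives about 1 in 20. Cxcl13 read 1.99 at 6 weeks, Il1rn 0.44 at 1 week, Ms4a1 0.33 at 1 week, Fcer1a 0.26 at 6 weeks and Eif2ak2 0.45 at 4 weeks. Relative to normal, the median of T cell markers was 0.89 at 1 week, of neutrophil and mast cell markers 0.19 at 1 week, of interferon-stimulated genes 0.19 at 6 weeks and of skeletal muscle markers -0.059 at 1 week.

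In 11 of 29 lists the difference between E. coli and saline had opposite signs at different weeks, and none of these differences was tested. The lowest and highest medians were -0.0068 and 0.75 for neutrophil and mast cell markers, -0.085 and 0.081 for podocyte and mesangial markers, -0.015 and 0.094 for endothelial markers, and -0.30 and 0.03 for fatty acid oxidation. They were -0.074 and 0.22 for proliferation, -0.19 and 0.07 for oxidative stress, -0.11 and 0.04 for erythroid, -0.040 and 0.15 for adipose, -0.15 and 0.02 for skeletal muscle and -0.16 and 0.12 for adrenal markers. In 2 of the 11 (proximal tubule and oxidative stress) both medians lay outside the central 95% of random lists.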

How the results depend on the processing

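Keeping exact zeros or control-like rows, and a slope per treatment, were added after the data were seen. The cause of the changes below was not tested. By design, the slope fit takes change over weeks out of the noise and tests the difference at the mean of weeks 1, 2 and 4. The week block rests on 3 matched pairs, and leaving out an array leaves fewer samples. The 32 features called between E. coli and saline became 83 after scaling (all 32 shared), 14 with exact zeros kept, 0 with week as a block (2396 at an unadjusted p under 0.05), 784 with a slope per treatment and 1 to 38 without single arrays. With week as a linear covariate 36 were called, of which 23 were shared. The 10 features called between E. coli and normal became 49 after scaling, 4 without features over 1.5-fold off on the normal array, 27 with each probe on its own and 5 to 24 without single arrays. The 2 called between saline and normal became 0, 7 and 2 to 4 under the last 3 of these and 5 with exact zeros kept. Against 0 in place of the normal array the counts were 11871 for E. coli and 9158 for saline, which include dye bias. The normal array itself could not be left out. The 18 gene lists became 0 with an estimated correlation and 4 with fry, and numbered 16 to 20 otherwise, though not always the same lists. Of the 18, 16 kept their call there. TGF-beta and growth factors lost it without any of 4 arrays (adjusted p from 0.05003 to 0.117) and proximal tubule markers without the saline array of 1 week (0.117) or with the normal-array filter (0.0552). Proliferation, adrenal, neutrophil and mast cell, and adipose markers each gained one, the adrenal markers also with that filter (0.0373). Both week trends stayed at 0 calls under every alternative run. Of 302 settings of the 19 called named genes, 177 kept the call, 125 lost it and 0 changed direction. Among uncalled genes Atp6ap2 (-0.33) changed sign to 0.052 with exact zeros kept, and ranged from -0.36 to 0.097 without single arrays, the latter without the saline array of 4 weeks. The endothelial median at week 1 (0.094) became -0.045 without features over 1.5-fold off on the normal array. Signal over background was not available to set limits for dim probes.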

Other observations

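The test of lymphoid against myeloid genes was chosen after the list medians were seen. Genes of B and plasma cells went both ways over the E. coli weeks. Of 8 measured, 2 had falling and 2 rising slopes at an unadjusted p under 0.05. Jchain read 2.40 at 1 week and 5.08, 4.98 and 5.55 at 2, 4 and 6 weeks. Ms4a1, a B cell surface protein, read 0.33 and then 0.96, 1.03 and 1.07, but was not among those 2 rising (limma, unadjusted p = 0.0573). It averages 2 probes whose E. coli minus saline differences were 1.46 and 0.24. Cd37, of the same list, read 1.35, 1.34, 1.07 and 0.88, and Spib 2.05, 1.67, 1.51 and 1.28. Il1b read 2.83, 2.86, 1.33 and 0.81 at the same weeks, C3 3.42, 3.52, 2.49 and 1.68, and Lcn2 4.29, 4.32, 3.39 and 2.78. These are single arrays, and no slope passed the threshold. The readings are not corrected for the normal array, where these genes read from -0.82 (Il1b) to 0.74 (Lcn2).

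Relative to the single normal array, proliferation genes had medians of 0.60, 0.31, 0.17 and 0.04 on the E. coli arrays in order of week and 0.30, 0.41 and 0.18 on the saline arrays. Tubular injury genes had medians of 1.24, 1.17, 0.85 and 0.41 and of 0.37, 0.43 and 0.64. Both arms share that array, so an error on it raises both alike, and the shared sign was not tested.

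A hypothesis was that lymphoid genes (33 of the T, B and plasma cell lists) persisted while myeloid genes (26) faded, against a single common fall in the share of leukocytes. The myeloid genes included the leukocyte phosphatase Ptprc, so these groups were not fully separated by cell type. The lymphoid minus myeloid median was -0.22, -0.37, 0.12 and -0.03 at 1, 2, 4 and 6 weeks, a slope of 0.07 per week. By an exact two-sided permutation of the weeks its p was 0.375, where the smallest possible was 0.0417. The data therefore do not separate a persistence of lymphoid genes from a common fall. A first version of the test shuffled genes between the lists and gave a very small p. It was dropped because genes measured on the same 4 arrays are not independent replicates.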
